A study of Homo sapiens with 6 samples.

How the data were processed

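RNA from SKOV3 cells, an ovarian cancer cell line, was sequenced after removal of ribosomal RNA in 3 control and 3 DDX18 knockdown libraries, per the labels. Total RNA was extracted with TRIzol, and the library kit named in the labels is a TruSeq Ribo Profile kit. The submitters' processing notes name HISAT2 2.2.1 and the builds GRCh38 and hg38. The counting tool, its strand setting and the annotation release are not given in the sources used here. The titles call the controls siControl and the knockdown samples shDDX18, 1 control title names SKOV5 where its cell line label says SKOV3, and the kind of silencing RNA and its sequence are not stated elsewhere.

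The deposited table holds 35615 genes with 6 columns of signal, that is, read counts per gene that the authors divided by 1 size factor per library. This was read from the values: in every column 100% of the values are whole multiples of 1 step, within 0.01 read, and the steps equal the inverse of median-of-ratios size factors recomputed from the recovered reads. The columns carry short names, nc1 to nc3 and si1 to si3. The first 3 were taken as the controls (nc as negative control) and the last 3 as the knockdown libraries. These names do not match the titles letter by letter, so libraries are numbered here as the columns are, and the DDX18 level was looked at as a check on the labels, not to set them. Every gene in the table matched GENCODE release 29 by chromosome, start, end and strand, and its deposited length equals the union of its exons there. A spreadsheet had turned 24 gene names into dates, and these were restored from the coordinates. Symbols are those of that release.

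The recovered reads came to 37661525 to 47583876 per library. Depth is therefore similar between libraries. How the precision of a gene's value depends on its level was not tested. The design fixed edgeR for counts and limma-trend for normalized values such as CPM, and did not foresee counts divided by size factors. As the deposited unit is a normalized one, the test for normalized values was used: limma-trend 3.58.1 in R 4.3.3 on log2(value + 1), for the 29819 genes with a mean value of at least 1, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Unless stated otherwise, adjusted p-values come from this fit. Fold changes on the log2(value + 1) scale understate the change of low genes. The DDX18 value also had an exact two-sided permutation test. For 34 gene lists, camera with a preset inter-gene correlation of 0.01 compared the members with all other tested genes, with adjustment over the lists, beside camera with an estimated correlation and fry. A list member that rose or fell passed the threshold over all genes tested. These lists, tests, filters and alternatives were fixed before the data were examined, except where stated. The tests of possible explanations were chosen after the patterns they address were seen. Among them are the word scan, the tests on ribosomal protein genes and the list of TGF-beta response genes.

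The genes named are DDX18, the 12 largest rises and 12 largest falls by log2 fold change among genes past the threshold that have a symbol, a mean above the median of the tested genes and no overlap between the groups, and in each list up to 4 members with the smallest adjusted p. Pseudogenes and clone names were counted and not named. Some genes that this rule selects are not reported here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Libraries of a group differed by more than sampling noise, with chi-square per gene between 5.11 and 8.18.

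Alternatives were no filter, a mean value of at least 5, a pseudocount of 0.1, quantile normalization, each library left out in turn, the replicate number as a block, a test against a fold change of 1.5, and exclusion of mitochondrially encoded, ribosomal protein and non-polyadenylated genes with rescaling of the rest to equal totals. Chosen after seeing the data were edgeR 4.0.16 (TMM, RLE and library sizes only) and DESeq2 1.42.0 on the recovered reads, and a fit without genes holding a 7-base word in the 3' untranslated region (UTR). Data were simulated for the comparison of knockdown and control with the real means, depths and dispersions. The changed genes had means of at least 10. In these data limma-trend on 29452 genes recovered 44% of genes changed 1.25-fold, 46% at 1.5-fold, 76% at 2-fold and 92% at 4-fold (50 genes each). There were 14 false calls among 143, a larger share than the threshold of 0.05 aims at. Far fewer genes were changed in the simulation than the 5419 called in the real comparison. Adjustment is stricter when few genes change, so these recovery rates do not carry over to the real comparison.

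For the word scan, each of 16282 words of 7 bases was tested for its presence in the 3' UTR of 11019 protein-coding genes with a mean value of at least 100 and a 3' UTR of at least 50 bases, from the transcript with the longest coding sequence. The log2 change, limited to 2 in either direction, was regressed on presence with 3' UTR length, GC content and gene level as covariates, and the fold changes were shuffled over genes 100 times. Another 387 genes had too short a 3' UTR and were not searched. The genes named were looked up for the top word at any level, where their 3' UTR was long enough. On shuffled fold changes with 1 planted word that lowered its genes by 0.1, the scan over these 11019 genes put the planted word first in 10 of 10 runs. The scan used Python 3.11.15 with numpy 2.4.6.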

Results

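Gene expression was measured by RNA sequencing of ribosomal RNA-depleted libraries from SKOV3 cells, a human ovarian cancer cell line. The 6 libraries comprised 3 controls and 3 with knockdown of DDX18, a DEAD-box RNA helicase of the nucleolus. The series title places DDX18 in the context of platinum resistance, and the comparison asks which transcripts differ when its level is lowered. No platinum treatment is named in the labels. Library depth was 37661525 to 41636404 reads in the controls and 41952328 to 47583876 after knockdown, as recovered from the normalized counts. Values below are normalized counts, given as mean ± SD over 3 libraries per group.

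DDX18 (ENSG00000088205.12, chromosome 2, 117814650 to 117832379, plus strand, GRCh38) fell from 10564 ± 331 to 1232 ± 68.7 normalized counts (SD, n = 3 per group). The knockdown libraries held 11.7% of the control level, a log2 change of -3.10 (SE 0.053; limma adjusted p = 2.13e-28). Control libraries ranged from 10218 to 10878 and knockdown libraries from 1153 to 1280, so the libraries labelled as knockdown lay on the side their labels give. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

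DDX18 knockdown was accompanied by changes in many genes, most of them small, and the larger changes were more often falls. Of 29819 genes tested, 5419 (18.2%) passed the threshold, of which 2913 rose and 2506 fell. This balance turned with the scaling: 2453 rose and 2844 fell with mitochondrial, ribosomal protein and non-polyadenylated genes excluded and totals rescaled, and 2751 rose and 2866 fell with edgeR on library sizes only. The median size of a called change was 0.34 on the log2 scale. Among called genes 351 rose and 870 fell by at least 1.5-fold, and 109 rose and 400 fell by at least 2-fold. The 2-fold rises numbered 56 without knockdown library 3 and the 2-fold falls 263 without control library 1, and DESeq2 gave 63 and 251. After quantile normalization 457 rose and 705 fell by at least 1.5-fold. Tested against a fold change of 1.5 in place of 0, 183 genes passed, 43 up and 140 down. The groups did not overlap in 30.1% of tested genes, against 10% by chance for 3 against 3 libraries. Of 16138 protein-coding genes, 2745 rose and 2211 fell. The first principal component carried 69.3% of the variance over 12438 genes with a mean of at least 100.

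**Figure D1:**
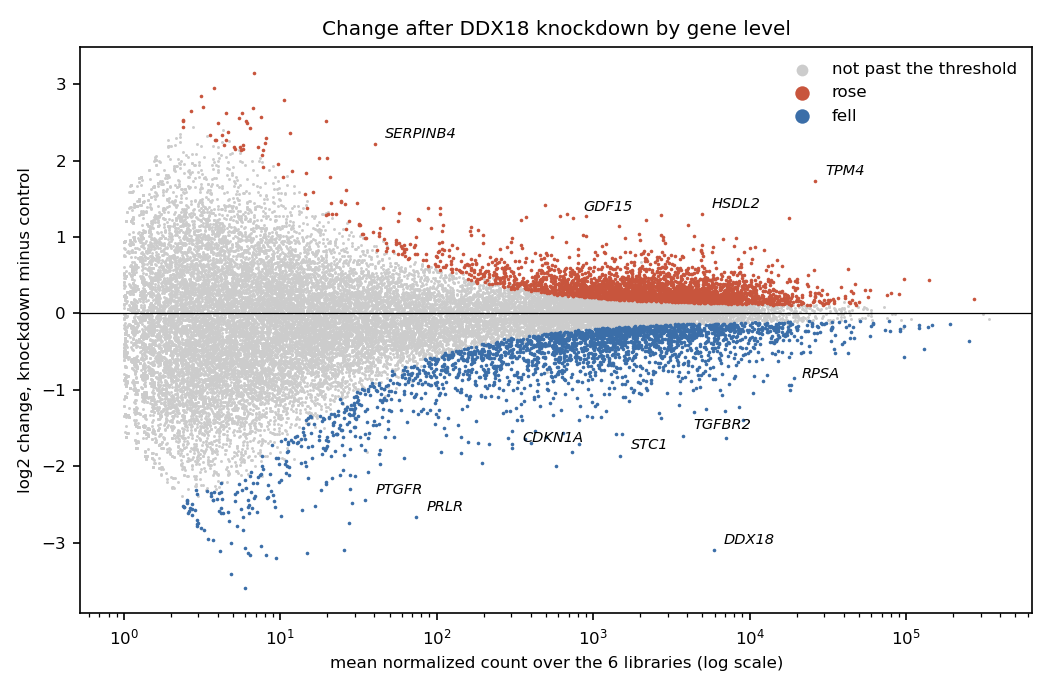
Log2 change (knockdown minus control, on the log2(value + 1) scale) of each tested gene against its mean normalized count over the 6 libraries on a log axis; orange points rose, blue points fell and grey points did not pass the threshold. DDX18 lies at -3.10, TPM4 at 1.73, and 870 of the blue points but 351 of the orange ones changed by at least 1.5-fold.

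Among the largest rises at sizeable expression was TPM4 (ENSG00000167460.15, chromosome 19, 16067021 to 16103005), which encodes a tropomyosin of the actin cytoskeleton and went from 12153 ± 296 to 40366 ± 874 normalized counts, 3.32-fold higher (adjusted p = 7.86e-26). HSDL2, a peroxisomal dehydrogenase-like protein, rose from 2853 ± 70.8 to 7035 ± 111. OGFR, the opioid growth factor receptor, rose from 1569 ± 71.1 to 3830 ± 146, and CHST14, a dermatan sulfotransferase, from 524 ± 44.3 to 1270 ± 33.4. Histone genes HIST3H2A (2.64-fold), HIST1H2AC (2.46-fold) and HIST1H2BJ (2.49-fold) were also among the 12. SERPINB4, a serpin of squamous epithelia, had the largest rise of the 12 on the log2 scale, at a low level, from 15.1 ± 10.9 to 65.0 ± 17. TDO2, which opens the tryptophan breakdown pathway, went from 59.1 ± 16.4 to 152 ± 19.5, and C3orf80 from 34.1 ± 17.2 to 80.7 ± 15.7. LINC00847 and MED11 overlap HEIH and CXCL16, so their reads may be shared; they rose 2.49-fold and 2.65-fold.

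Among the largest falls, STC1 (ENSG00000159167.11, chromosome 8, 23841915 to 23854807), encoding the secreted glycoprotein stanniocalcin, went from 2333 ± 128 to 643 ± 52.5 normalized counts (adjusted p = 8.57e-19). TNS1, a focal adhesion protein, fell from 1146 ± 40.9 to 325 ± 20.8, and RBMX2, a splicing factor, from 922 ± 116 to 237 ± 70.3. PRLR, the prolactin receptor, fell from 128 ± 13.3 to 19.5 ± 3.91, a log2 change of -2.67. ARHGEF6, an exchange factor for small GTPases, fell from 223 ± 16.6 to 63.9 ± 20, and UNC5A, a netrin receptor, from 97.9 ± 4.94 to 26.4 ± 8.45. Control means between 54.4 and 69.1 were found for 5 further genes of this set, the prostaglandin receptor PTGFR, the prostaglandin-degrading enzyme HPGD, the cytokine IL37, the epidermal gene SPRR2A and MMP19, which overlaps TMEM198B. PEG10, which overlaps SGCE, fell from 165 ± 23.4 to 48.0 ± 16.9. The 3' UTRs of PTGFR, STC1, HPGD and ARHGEF6, 4 of the 11 falls searched, hold the 7-base word AACATCA, which also occurs in the DDX18 coding sequence. None of the 11 rises searched holds it. The word was picked because genes that hold it fell in these same data, so this contrast is partly built in. Of 11019 genes scanned 1296 hold it, and 19.0% of the words tested occur in the DDX18 transcript.

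**Figure D2:**
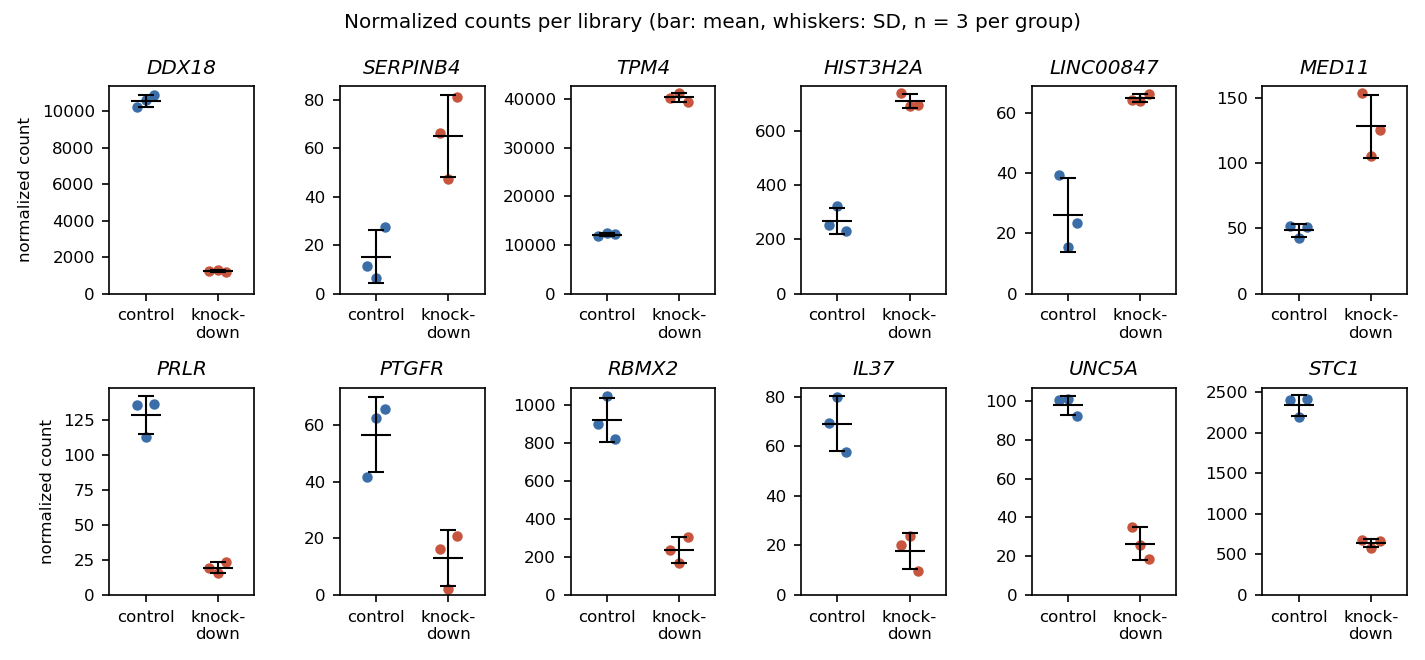
Normalized counts of DDX18, 5 of the largest rises (upper row) and 6 of the largest falls (lower row) in each library; points are libraries, the bar is the mean and whiskers are the SD over 3 libraries per group. In each of the 12 panels the groups do not overlap, as with TPM4 at 12153 against 40366.

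Lists of functionally related genes were examined as groups. Of 34 lists, 11 passed the camera threshold, 7 up and 4 down. With an estimated inter-gene correlation 0 did (3 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 13, of which 8 are among the 11. Counts of members that rose or fell are over all genes tested. Counts adjusted over the list alone are given where they differ. Camera was not adjusted for gene level. The median log2 change was -0.03 over all tested genes. It was 0.07 over the 1915 genes outside the ribosomal protein list with a mean of at least 5000.

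Genes of ribosome production moved in both directions. Of 108 ribosome biogenesis factors, 28 rose and 11 fell (30 and 15 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0707). It passed with no filter (adjusted p = 0.0388), without control library 2 (adjusted p = 0.0183) and without knockdown library 3 (adjusted p = 0.00657). NOLC1, a nucleolar chaperone of small nucleolar ribonucleoproteins, rose from 4583 ± 217 to 8991 ± 195, and TCOF1, a factor for ribosomal RNA transcription, rose 1.57-fold. DHX37 rose 1.44-fold, as did TSR2, which overlaps FGD1, by 1.49-fold. Cytosolic ribosomal protein mRNAs shifted downward by small amounts: 30 of 79 fell, none rose, 74 had a negative value and the median log2 change was -0.11. Adjusted over the list alone 38 fell and 1 rose. The list passed camera (adjusted p = 5.94e-11; adjusted p = 0.658 with an estimated correlation). RPSA stood apart from the others, falling from 24327 ± 1274 to 12737 ± 493, and its 3' UTR holds the word AACATCA; RPL37A fell by 0.35 and RPS27 by 0.24 on the log2 scale. In the RNA polymerase I machinery 3 of 20 rose and 3 fell, with POLR2E at -0.45 and POLR1B at 0.29. Of 37 DEAD-box helicases other than DDX18, 7 rose and 3 fell (8 and 4 adjusted over the list alone), including DDX54 (0.32) and DDX39A (-0.43). Of 19 snoRNA host genes 3 rose, SNHG7 by 1.56-fold, and 1 fell, with a mean of 0.06 but a median just below 0. By limma 0 of the 8 non-polyadenylated RNAs passed, and 0 had an unadjusted p under 0.05 (NEAT1 log2 change -0.09, adjusted p = 0.217). As a list they passed fry downward (adjusted p = 0.0269, mean log2 change -0.23) but not camera (adjusted p = 0.480). Ribosomal RNA genes, with mitochondrial ones and ribosomal RNA pseudogenes included, took 0.785% to 0.803% of normalized counts in controls and 0.578% to 0.622% after knockdown. This share was not split by kind, and the libraries were depleted of ribosomal RNA, so it does not measure cytosolic ribosomal RNA.

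DNA repair lists, relevant to how cells process platinum adducts, did not pass camera as groups. By fry, which asks only whether a list's own genes move one way, Fanconi anaemia and nucleotide excision repair (adjusted p = 0.0269 each) and end joining and R-loop factors (adjusted p = 0.0345 each) passed upward. Without genes holding AACATCA, a word picked because its holders fell, homologous recombination (adjusted p = 0.0195) and Fanconi anaemia (adjusted p = 0.0377) passed camera upward. In homologous recombination 12 of 50 rose and 4 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.103). RMI1, part of the complex that dissolves Holliday junctions, fell from 1645 ± 89.3 to 1045 ± 23.0, and RPA2, a single-stranded DNA binding protein, fell 0.37 on the log2 scale, while UIMC1 and BABAM2, members of the BRCA1-A complex, rose by 0.36 and 0.43 (BABAM2 overlaps MRPL33). In the Fanconi anaemia pathway 8 of 30 rose and 2 fell: CENPX, which overlaps LRRC45, from 770 ± 20.3 to 374 ± 31.7, and ERCC4, a nuclease shared with nucleotide excision repair, from 860 ± 69.2 to 472 ± 85.8. FANCI rose 1.20-fold and FANCF 1.48-fold. Nucleotide excision repair had 5 rises, RAD23B and GTF2H3 among them, and 4 falls of 31, with a median of 0.03, a mean of -0.01 and camera's direction up. End joining had 6 rises and 3 falls of 22, with XRCC5 and XRCC6 at 0.21 and 0.22 and XRCC4 at -0.54. The ATR response had 6 rises and 2 falls of 20, with ETAA1 at 0.58 and CLSPN at -0.36, a median of -0.01, a mean of 0.04 and camera's direction up. Among R-loop processing factors 4 of 27 rose (6 adjusted over the list alone) and 2 fell, RNASEH2B rising 1.26-fold. The 3' UTRs of RMI1, ERCC4 and XRCC4 hold AACATCA.

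Platinum transport and detoxification genes had 7 rises and 5 falls of 32 and did not pass as a list (camera adjusted p = 0.739, with camera's direction up but a mean of -0.07 and a median of -0.01). GCLM, the modifier subunit of the enzyme that makes glutathione's precursor, rose from 2759 ± 177 to 4627 ± 109, and GCLC and GSTP1 rose by 0.34 and 0.31 on the log2 scale. MT2A, a metallothionein, fell from 11947 ± 1049 to 7811 ± 936. Targets of the antioxidant regulator NRF2 passed camera upward with 17 rises and 2 falls of 32, or 19 and 3 adjusted over the list alone (adjusted p = 1.59e-05; adjusted p = 0.423 with an estimated correlation). NQO1 rose 1.33-fold and PIR 1.64-fold, and NAMPT, whose 3' UTR holds AACATCA, fell to 0.753 of control. Integrated stress response genes also passed upward, 17 rising and 2 falling of 41, or 19 and 2 adjusted over the list alone (adjusted p = 4.70e-06; adjusted p = 0.423 with an estimated correlation). GDF15, a stress-induced cytokine, rose from 437 ± 36.3 to 1041 ± 53.3, CTH, of cysteine synthesis, from 1071 ± 72.8 to 2125 ± 13.9, and TRIB3 1.74-fold. The unfolded protein response had 9 rises and 4 falls of 29; the chaperones CALR and CANX fell by 0.37 and 0.32 and HSPA5 rose by 0.22.

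The heat shock list passed upward with 8 rises and 2 falls of 21 (adjusted p = 0.0211; adjusted p = 0.658 with an estimated correlation), HSP90AA1 rising by 0.25 and HSPA1B, near-identical to HSPA1A, by 0.41. It did not pass without control library 3 (adjusted p = 0.0761) or knockdown library 1 (adjusted p = 0.0668). Nor did it pass on the recovered reads with TMM (adjusted p = 0.135) or with a mean value of at least 5 (adjusted p = 0.0688). The list's median log2 change of 0.04 was below that of genes with a mean of at least 5000 (0.07). p53 target genes were split, 8 rising and 9 falling of 40 (9 and 9 adjusted over the list alone). The cell cycle inhibitor CDKN1A fell from 467 ± 59.0 to 138 ± 27.0 and CCNG1 from 3760 ± 192 to 1525 ± 33.0, while IGFBP3 rose from 8926 ± 195 to 15851 ± 531. Apoptosis regulators had 8 rises and 6 falls of 38, or 10 and 7 adjusted over the list alone, with a median of 0.06, a mean of -0.03 and camera's direction up. The TRAIL receptor gene TNFRSF10B fell from 11041 ± 316 to 7662 ± 152 and BIRC3 from 1249 ± 22.0 to 754 ± 12.7. CCNG1 and TNFRSF10B hold AACATCA in their 3' UTRs.

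Genes of G1/S and DNA replication passed upward with 13 rises and 4 falls of 54, or 14 and 4 adjusted over the list alone (adjusted p = 0.0179; adjusted p = 0.342 with an estimated correlation), RRM2 rising 1.29-fold and CHAF1B 1.36-fold. The list did not pass with a mean value of at least 5 (adjusted p = 0.0511). Nor did it pass on the recovered reads with TMM (adjusted p = 0.120) or after quantile normalization (adjusted p = 0.466). Its median log2 change of 0.06 was no higher than that of genes with a mean of at least 5000 (0.07). G2/M genes had 10 rises and 15 falls of 71 (11 and 15 adjusted over the list alone), the motor protein KIF11 and the checkpoint protein MAD2L1 falling by 0.63 each, and the 3' UTR of MAD2L1 holds AACATCA. This list passed downward only after quantile normalization (adjusted p = 0.0118). Replication-dependent histone genes had 8 rises and no fall of 44 (adjusted p = 0.0285; adjusted p = 0.484 with an estimated correlation), led by HIST1H2AC and HIST1H1C (840 ± 17.2 to 1582 ± 78.7). The histone list did not pass without control library 3 (adjusted p = 0.0661) or knockdown library 1 (adjusted p = 0.0668). Its mean log2 change was 0.13, but 0.05 with a pseudocount of 0.1 and 0.28 with a mean value of at least 5. It passed in both settings, but low members weighed on its mean.

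Mesenchymal and matrix genes passed downward with 20 falls and 5 rises of 49, or 22 and 5 adjusted over the list alone (adjusted p = 2.26e-06; adjusted p = 0.342 with an estimated correlation; median log2 change -0.18). TGFBR2, a TGF-beta receptor, fell from 5618 ± 147 to 1852 ± 69.1, CD44 from 14536 ± 528 to 9627 ± 328, and THBS1 from 2510 ± 114 to 1345 ± 110. TGFBR2 and CD44 hold AACATCA in their 3' UTRs. Epithelial genes were split, 6 rising and 8 falling of 29 (6 and 10 adjusted over the list alone), with ELF3 1.67-fold higher and AP1M2 at 0.682 of control. Among ovarian cancer and SKOV3 markers 3 of 17 rose and 7 fell: MUC16, which encodes the antigen CA125, fell from 1399 ± 98.9 to 560 ± 159, and ERBB2, which SKOV3 cells carry in amplified form, rose from 81709 ± 6776 to 111790 ± 8328. Of 14 fibroblast and endothelial markers, KDR fell from 146 ± 20.7 to 60 ± 4.42, COL3A1 rose from 50.9 ± 15 to 92.3 ± 18.6, and PDGFRB was at 0 in each control library and 5.35 ± 1.16 after knockdown. COL3A1 lost its call without control library 2 and without knockdown library 1 or 3, and PDGFRB without any 1 knockdown library. By limma 0 of 12 immune cell markers passed, and 1, CD14 (45.2 ± 14.2 and 22.3 ± 5.32), had an unadjusted p under 0.05; edgeR called it on the recovered reads.

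Inflammatory genes of the NF-kB list had 4 rises and 7 falls of 27, or 6 and 9 adjusted over the list alone. Log2 changes were -0.60 for IL1B, -0.51 for IL1A and -0.65 for TNFAIP3, and CSF1 rose 1.54-fold. Interferon-stimulated genes depended on single control libraries. With all libraries 2 of 50 rose and 7 fell (mean -0.15, camera adjusted p = 0.318). Without control library 2 the mean was 0.06 with camera upward (adjusted p = 0.0345), and without control library 3 it was -0.36 with camera downward (adjusted p = 1.78e-06). IFI44L shows the spread, with 104, 239 and 77.5 normalized counts in the controls and 50.3 to 60.3 after knockdown. It lost its call without control library 2, and its 3' UTR holds 2 copies of AACATCA.

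Metabolic lists moved apart. Cholesterol biosynthesis passed upward with 13 rises and 3 falls of 25 (adjusted p = 0.000712; adjusted p = 0.342 with an estimated correlation), INSIG1 rising 1.33-fold, while the sterol transporter gene STARD4, whose 3' UTR holds AACATCA, fell from 2426 ± 171 to 1213 ± 14.6. Glycolysis and hypoxia genes passed downward with 14 falls and 3 rises of 34, or 17 and 4 adjusted over the list alone (adjusted p = 0.000238; adjusted p = 0.506 with an estimated correlation). Hexokinase HK2 fell from 1708 ± 89.5 to 707 ± 33.3 and LDHA from 150970 ± 1907 to 109700 ± 1948; LDHA holds the word as well. Of 13 mitochondrially encoded mRNAs 9 fell, or 10 adjusted over the list alone, and 0 rose (adjusted p = 5.21e-06; adjusted p = 0.423 with an estimated correlation), MT-ND6 by 0.35 and MT-ATP6 by 0.24, and mitochondrial genes took 4.03% to 4.27% of counts in controls and 3.55% to 3.64% after knockdown. Nuclear oxidative phosphorylation genes had 7 rises and 2 falls of 66 (adjusted p = 0.06). SDHC rose by 1.29-fold although its 3' UTR holds AACATCA. The list passed without control library 2 (adjusted p = 0.00120), knockdown library 2 (adjusted p = 0.0393) or knockdown library 3 (adjusted p = 0.0126). It also passed with no filter (adjusted p = 0.0388) and with the replicate block (adjusted p = 0.0487). Mitochondrial ribosomal proteins passed upward with 18 rises and 7 falls of 76, or 28 and 8 adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.658 with an estimated correlation), MRPL49 at 0.34 and MRPL11 at -0.58, but not without control library 3 (adjusted p = 0.156) or on the recovered reads with TMM (adjusted p = 0.0765).

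**Figure D3:**
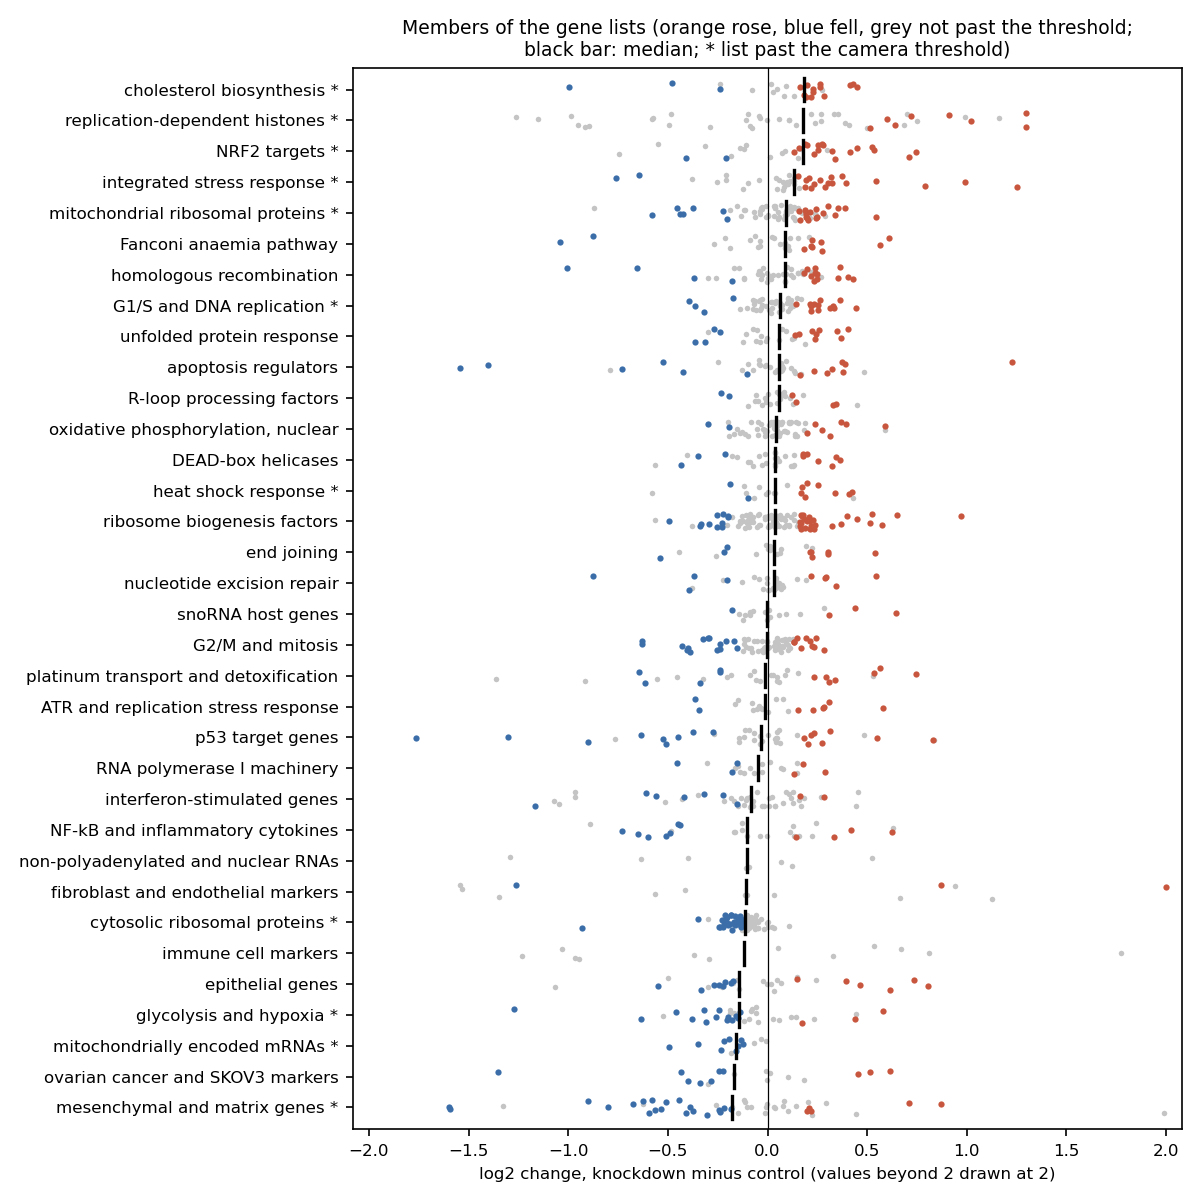
Log2 change (knockdown minus control) of each member of the 34 gene lists, ordered by the list's median, which is the black bar; orange members rose, blue members fell, grey members did not pass the threshold, values beyond 2 are drawn at 2, and an asterisk marks the 11 lists past the camera threshold with its preset correlation. Mesenchymal and matrix genes have the lowest median (-0.18), and 74 of the 79 ribosomal protein genes lie below 0.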

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

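The fits with edgeR and DESeq2 on recovered reads and the fit without genes holding the word AACATCA were chosen after seeing the data. DDX18 stayed past the threshold in each alternative run for it, with a log2 change between -3.14 and -3.05. The 5419 changed genes became 4994 to 6275 under the other filters, pseudocount, quantile normalization, gene sets and replicate block, 4351 to 4896 with 1 library left out, 5380 to 5648 with edgeR or DESeq2, and 4657 without genes holding the word. DESeq2 gave no adjusted p for 18643 genes. Of the 5419, edgeR with TMM also called 5267 and DESeq2 5091, in the same direction. Against a fold change of 1.5 the count was 183, since that test asks for larger changes. The replicate block gave 6275 genes and 12 lists, the added one being nuclear oxidative phosphorylation. Same-numbered libraries deviated together with correlations of 0.109, 0.0841 and 0.179. The other pairs between the groups had lower ones, from -0.166 to 0.0653. These correlations are weak and nothing in the labels pairs the libraries, so pairing stays open.

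Of 145 named genes past the threshold, 136 to 145 kept direction and call in the fits against no change that used all genes or other filters, and 122 without genes holding the word, where those genes were left out. They were not counted in the test against a fold change of 1.5. Exclusion of mitochondrial, ribosomal protein and non-polyadenylated genes gave the 136 for the same reason in part. Marker genes past the threshold numbered 25, and 17 to 22 with 1 library left out. Lists past the threshold numbered 11 with camera, 0 with an estimated inter-gene correlation and 13 with fry, which kept 8 of the 11 and added 5 others. Excluding those genes left 6 lists, as 2 of the 11 went with their genes and 3 lost their call; the cause was not tested. Leaving out 1 library gave 9 to 14 lists. Interferon-stimulated genes reversed to a mean of 0.0628 without control replicate 2 and passed downward at -0.355 without control replicate 3. How recovery depends on depth or gene level was not tested. On simulated data with changed genes at means of at least 10, 46% of 1.5-fold changes were recovered. Those data held far fewer changed genes than were called here, so this rate does not carry over.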

Other observations

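Chosen after the word scan was seen were the comparison by number of copies, the scan and the share of falls without the 6-base core or another such word, and the list test without genes that hold the word.

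The 3' UTR word AACATCA was picked in a scan of these same fold changes, so a lower value of its holders is how it was found. With 0, 1 and at least 2 copies (9723, 1094 and 202 genes) the median log2 changes were 0.05, -0.09 and -0.14, and 15.1%, 35.6% and 43.1% fell. The 1969 genes with a copy only upstream of the 3' UTR had a median of -0.03, and 25.7% of them fell. Unlike the scan, these group values were not adjusted for 3' UTR length, GC content or gene level. The word is in the 3' UTRs of TGFBR2, CCNG1, STARD4, ERCC4, RMI1 and RPSA, which fell, and of SDHC, which rose (0.37). It is not in those of CDKN1A, HK2, PRLR or TNS1. Named genes were looked up for this exact word only. They were not looked up for its core AACATC, which 2976 scanned genes hold against 1296 for the word. Without genes that hold it, mesenchymal and matrix genes still passed camera downward with its preset correlation (adjusted p = 8.35e-06). Among all genes that call was lost (adjusted p = 0.342 with an estimated correlation), and the estimate was not run without the word. In the same fit homologous recombination (adjusted p = 0.0195), Fanconi anaemia (adjusted p = 0.0377), ribosome biogenesis (adjusted p = 0.0261) and apoptosis lists (adjusted p = 0.0298) passed upward, which leaving out genes picked because they fell favours by construction. Falls were 68.8% of the 650 changes of at least 1.5-fold among scanned genes. They were 54.4% (exact 95% interval 49.0% to 59.6%) among genes without the core AACATC. Without any 1 of 689 other 6-base words of like frequency they were 58.4% at the lowest and 67.7% at the median. Words that overlap the core were not kept out of the 689. The core, unlike those words, was chosen for its tie to falls, so a lower share is partly built in.

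Falls of 1.5-fold or more outnumbered rises, and a candidate explanation is repression of other transcripts by the silencing RNA through its seed, the short stretch that pairs with 3' UTRs as in a microRNA. Over 16282 words of 7 bases AACATCA had the lowest statistic, -19.6, against -4.77 in 100 shuffles, and it occurs once in the DDX18 transcript (positions 1035 to 1041, coding exon 6, chromosome 2, 117822017 to 117822023), as 19.0% of tested words do. On the side of falls 22 words lay below the lowest of the shuffles. The second, CAACATC (-16.0), overlaps AACATCA in the DDX18 transcript, from position 1034. The third, AAACATC (-14.6), is not in that transcript. On the side of rises 4 words lay above the highest of the shuffles (6.18 against 5.54). Without genes holding the core AACATC the lowest statistic was -6.05 against -5.04, for GACATCA. That word is not in the DDX18 transcript but shares its last 6 bases with AACATCA. Low counts are argued against as the whole cause, since falls were 59.5% (exact 95% interval 53.6% to 65.1%) at means of at least 1000. The share of the excess that a seed would cover stays open, the sequence of the silencing RNA is not in the sources used here, genes below a mean of 100 were left out of the scan, and a response to lower DDX18 that favours the same transcripts stays open.

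For all changed genes, 1 of the 10 splits of the 6 libraries gave as many, the real one with 5419, the highest other gave 1, and 10 splits are too few for a share under 0.05.

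Of 79 ribosomal protein mRNAs 30 fell and 49 did not pass, and the list passed camera downward, a call lost with an estimated correlation (adjusted p = 0.658) and with fry (adjusted p = 0.139). Removal of a trend on GC content, exon length and level moved their median from -0.11 to -0.18 (77 of 79 below 0, SD between members 0.125), which argues against those trends. Other genes with a mean of at least 5000 had a median of 0.0689, which argues against scaling of abundant genes, and ribosomal protein pseudogenes gained -3.01% of the counts lost (42587 ± 1963 to 39037 ± 1234), which argues against reads moving to them. The list total went from 1342176 ± 73914 to 1224114 ± 44986 normalized counts (SD, n = 3 per group). Variation between these libraries and an effect of DDX18 both stay open.

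Of 49 mesenchymal and matrix genes 20 fell, TGFBR2 among them, 5 rose and 24 did not pass (list adjusted p = 0.342 with an estimated correlation), and lower TGF-beta signalling was tested as a hypothesis on 27 response genes outside that list. Their mean log2 change was -0.0639 and their median 0.02, with 5 rises and 7 falls. The camera p was 0.399, and 0.456 with an estimated correlation, so the hypothesis stays open. MYO10 (-1.07) and SMURF2 (-0.51), whose 3' UTR holds AACATCA, fell, ID1 (0.30) and RHOB (0.35) rose, and SMAD7 (0.02) and SKIL (0.06) did not pass the threshold.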
